A study of Drosophila melanogaster with 2 samples.

How the data were processed

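Each of the 2 samples was a two-colour comparative genomic hybridisation, in which larval salivary gland DNA and embryo DNA compete for the same probes. Per the labels, 3 µg of each genomic DNA was labelled by random priming after dissection of about 150 pairs of glands, and array 1 carried gland DNA in Cy3 and embryo DNA in Cy5, with the dyes exchanged on array 2. The arrays were of 1 design with 184672 spots, of which 5542 were control spots and left out.

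The deposited scanner files hold the intensity of each spot in both channels. Per the file headers, they were made with Agilent Feature Extraction 9.5.3.1 with an extended dynamic range on array 1 and 9.1.1.1 with a single scan on array 2, which makes software and array inseparable; the processed intensity is background-subtracted from negative controls with spatial detrending and dye-normalized by a linear factor on rank-consistent probes. The files also hold the log10 ratio of red over green deposited by the authors' scanner software, which was not used because the processed intensities give it. A deposited intensity table of each channel was equal to the median spot intensity of the scanner files at 100.0% of 179130 probes. The authors' deposited normalized values, a score scaled to a standard deviation of 1 over the probes of 1 array, were made with MA2C per the file name, with the direction not stated; their median was -0.042. The deposited list of troughs gives a score per trough from the same program, on the FlyBase r5.1 build per the file header; whether both arrays entered it is not given in the sources used here.

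For every probe the log2 ratio of the channel labelled salivary gland over the channel labelled embryo was computed from the processed intensities and centred on each array's median, without loess or quantile normalization, because copy number arrays may truly shift one way. Probes with an outlier flag were dropped from that array (250 on array 1 and 463 on array 2). Saturated probes (1 and 26) and probes not well above background in a channel (299 and 84) were kept. Probes were grouped into fixed bins of 10 kb, and a bin needed at least 5 probes on each array; the median bin held 16. The bin medians of the arrays were fitted with limma (lmFit with an intercept, then eBayes, two-sided; prior degrees of freedom 10.3) and adjusted by Benjamini-Hochberg over 11487 bins. A dye effect of equal size on both arrays cancels in the mean of the swapped arrays, but a part that differs between them does not. Intervals were runs of at least 3 called bins joined over gaps of up to 2 bins. The arrays come from separate extractions per the labels, and p-values reflect no spread beyond that between these. With 2 arrays, eBayes weighs the spread of each bin less than a prior fitted over all bins. Each p thus rests mostly on that shared spread.

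Deposited troughs were compared by the mean log2 ratio of their probes, and their median over troughs was tested by 10000 circular rotations along the joined arms. Correlations of interval length used 100000 permutations. The calling steps were tested on simulated bin values with the spread that limma fitted to the real bins. On the log2 scale, 67 of 67 bins changed by 0.75, 67 of 67 changed by 1.5 and 66 of 66 changed by 3 were recovered. There were 0 false calls among the unchanged bins, and 10 of 10 planted intervals were found. The simulated bins were independent and skipped the probe steps, so this checks the calling code and gives no error rate for the real data. Software was R 4.3.3, limma 3.58.1, the data.table package (1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

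The design, the tests, the rule for named regions and the alternatives were fixed before the data were examined. The rule named the 10 intervals with the strongest bins, the 5 highest called bins and up to 3 deposited troughs without a called bin. It was written for lower intervals; since none were found by the labels' dyes, it was applied to the higher ones, and positions stand in place of gene names because the files pair no probe with a gene and no annotation of their coordinates was used here. The 3 troughs were those with the highest deposited score. For the same reason the planned gene lists were not analysed here. The alternatives were normexp background correction (offset 50), loess within each array, each array left out, stricter probe filters, centring on the autosomal arms, bins of 5 and 20 kb, a correction for probe GC content (smooth span 0.3), a minimum effect of 1, a trended and robust variance prior, no joining of gaps, and stricter uses of the trough list. The deposited normalized values could not serve as an alternative because their scale is not log2. Troughs whose edges fell on no probe edges were left out, since coordinates were not converted between builds.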

Results

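The copy number of genomic sequences was compared between 2 DNA sources of the Oregon-R strain of Drosophila melanogaster: salivary glands of wandering larvae of instar 3 and embryos of 0 to 4 h. Salivary gland cells of late larvae are polytene: their chromosomes are copied many times without division, and late-replicating sequences are classically copied less than the rest (underreplication). Both DNAs were labelled with different dyes and hybridised together to an array of 179130 probes of 45 to 60 bases, spaced at a median of 620 bp on X, 2L, 2R, 3L and 3R and 630 bp on 4. There were 2 arrays, 1 per DNA extraction, with the dyes swapped between them. Array 1 had a median processed signal of 1433 in the channel labelled salivary gland and 1519 in the channel labelled embryo; array 2 had 1161 and 1113. The number of arrays limits the precision of every value (n = 2), and SDs are between the arrays. Positions are those of the array files, which state no genome build.

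The question the design poses is which parts of the genome differ in relative copy number between the gland and the embryo. In 569 of 11487 bins of 10 kb (4.95%) the channel labelled salivary gland was higher relative to the channel labelled embryo, and in 7 bins it was lower. This direction follows the dyes in the labels and is opposite to that of the authors' deposited list, which names such intervals troughs, so every signed value below is stated for the channels as labelled and changes sign if the dyes were recorded the other way round. The 569 bins had ratios above 0 on both arrays, and 273 of them reached a mean log2 ratio of 1 or more; no bin reached -1. Bins were called with limma at a Benjamini-Hochberg adjusted p below 0.05 and a mean log2 ratio of at least 0.5 in size. The adjusted p alone passed 864 higher and 234 lower bins. All 576 bins of at least 0.5 in mean size also passed the adjusted p, so the size set the counts of calls.

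**Figure D1:**
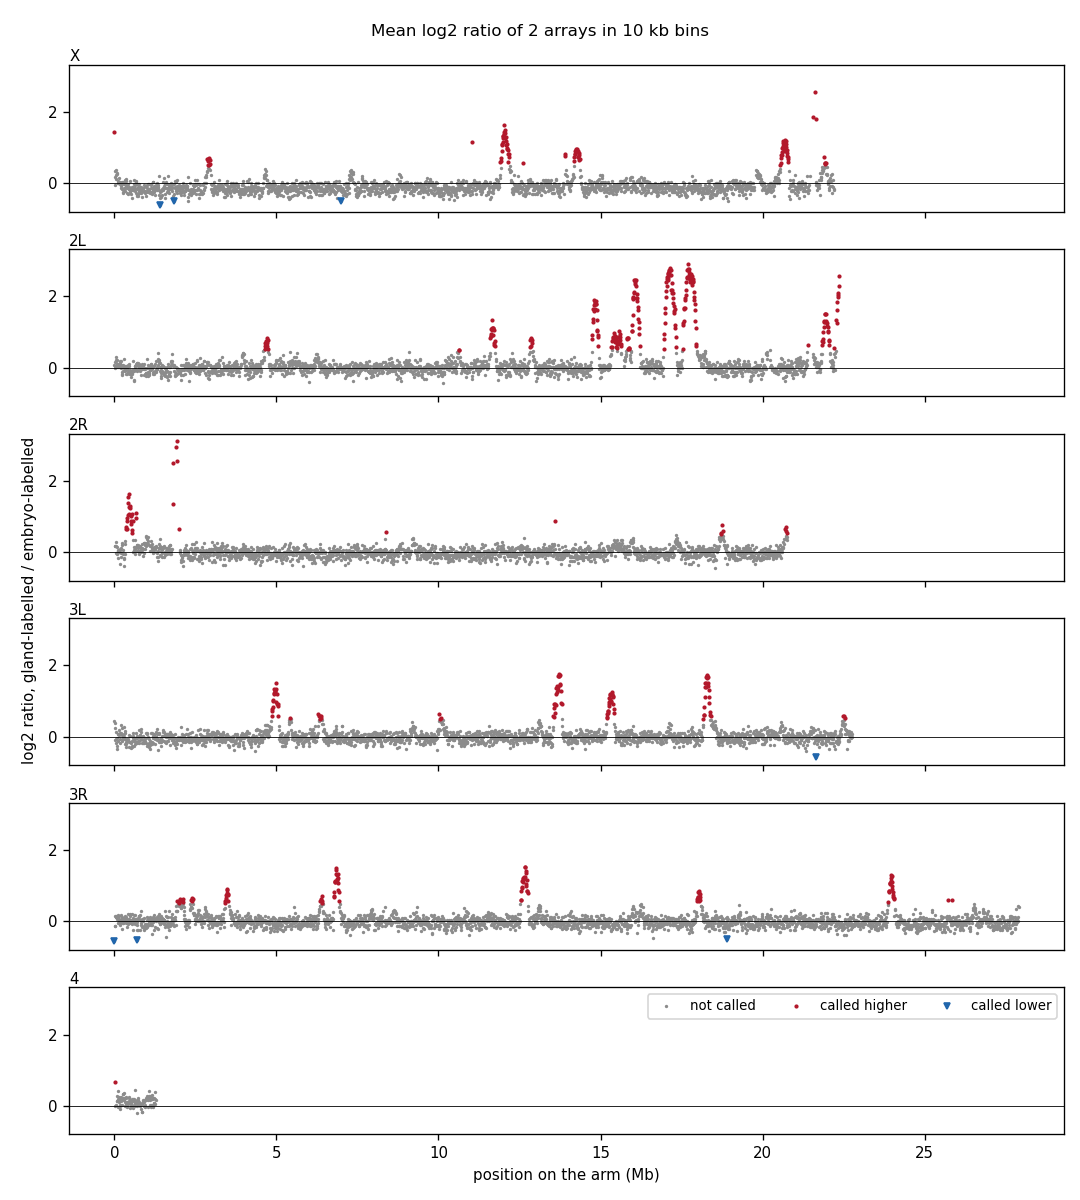
Mean log2 ratio of the channel labelled salivary gland over the channel labelled embryo on 2 arrays, in 10 kb bins along each chromosome arm (x axis, Mb), with one point per bin and called bins coloured. The 569 called higher bins stand in narrow groups that are most frequent on 2L, and the 7 called lower bins stand alone.

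The higher bins were clustered: 544 of the 569 lay in 36 intervals, each a run of at least 3 called bins, that covered 5840 kb in total. The intervals were 40 to 430 kb long (median 140 kb), and their peak bins had mean log2 ratios of 0.59 to 3.14 (median 1.12), so the channel labelled salivary gland was 2.18-fold higher at the median peak and 8.81-fold higher at the strongest. 2L held 11 intervals and 233 called bins, 10.7% of its bins, against 101 called bins (3.66%) on 3R, 104 (4.62%) on 3L, 92 (4.27%) on X and 38 (1.88%) on 2R. Of the 121 bins of 4, 1 was called higher and none formed an interval. No interval was made of lower bins.

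The 10 intervals with the highest peaks were 5 on 2L, 2 on 2R, 2 on 3L and 1 on X. The highest peak was that of a 40 kb interval of 2R at 1910001 to 1950000, with a mean log2 ratio of 3.14 ± 0.20 (SD, n = 2; limma adjusted p = 1.39e-08), or 8.81-fold. The longest interval, 2L 17530001 to 17960000, peaked at 2.90 ± 0.48 (adjusted p = 5.48e-08), and its neighbour at 2L 16940001 to 17330000 at 2.80 ± 0.33. The other 3 on 2L were at 22270001 to 22360000, the outermost bins tested at the centromere-proximal end, with a peak of 2.57 ± 0.49, at 15950001 to 16210000 with 2.47 ± 0.45, and at 14730001 to 14940000 with 1.90 ± 0.08. On 3L the peaks were 1.75 ± 0.26 at 13540001 to 13800000 and 1.74 ± 0.27 at 18170001 to 18400000. On X the interval 11900001 to 12180000 peaked at 1.64 ± 0.29, and on 2R the interval 350001 to 570000 at 1.62 ± 0.01. The limma adjusted p of these 10 peak bins was at most 6.94e-07. The 5 highest single bins were the peaks of the first 3 of these intervals and a second bin in each of the first 2: 2R 1910001 to 1920000 at 2.95 ± 0.46 and 2L 17680001 to 17690000 at 2.78 ± 0.24.

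**Figure D2:**
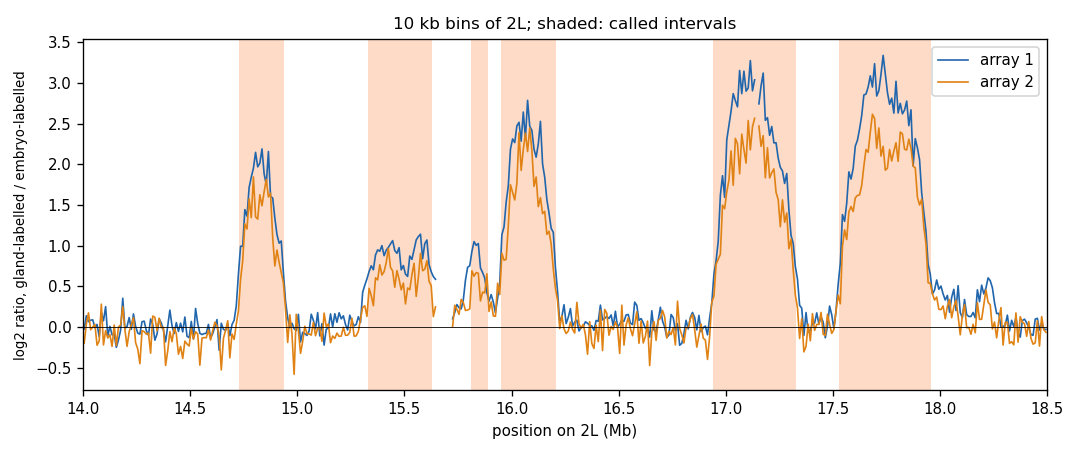
Log2 ratio of the channel labelled salivary gland over the channel labelled embryo in 10 kb bins of 2L (x axis, Mb), over the part of the arm that holds 6 of its 11 intervals, with one line per array; shaded spans are called intervals and breaks are bins with too few probes. Both arrays rise in the 6 plotted intervals, and the peak of the interval 17530001 to 17960000 reads 3.24 on array 1 and 2.57 on array 2.

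On average the ratio fell with distance from the peak bin and reached the level of the rest of the genome within 200 kb. Over the 22 intervals whose peak was at least 400 kb from any other interval and from the end of the arm, the mean log2 ratio was 1.30 ± 0.58 (SD between intervals) in the peak bin, 0.84 ± 0.38 at 50 kb, 0.37 ± 0.27 at 100 kb, 0.08 ± 0.16 at 150 kb and -0.01 ± 0.10 at 200 kb. Intervals of different lengths were averaged on their highest bin, so this mean does not show the shape of single intervals. Because the peak bin was chosen for its height, its own value is raised by the choice; with the peak chosen on array 1 and read on array 2 it was 1.02, against 1.15 on array 2 at the peak of the mean. Longer intervals had higher peaks across the 36 intervals (Pearson r = 0.598, permutation p = 0.00012; Spearman rho = 0.659, permutation p = 3e-05; 1 relation tested), and r was 0.413 without the 2 intervals whose length was farthest from the median. Interval length is set by the same threshold on the ratio, so length and height are not independent measures.

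**Figure D3:**
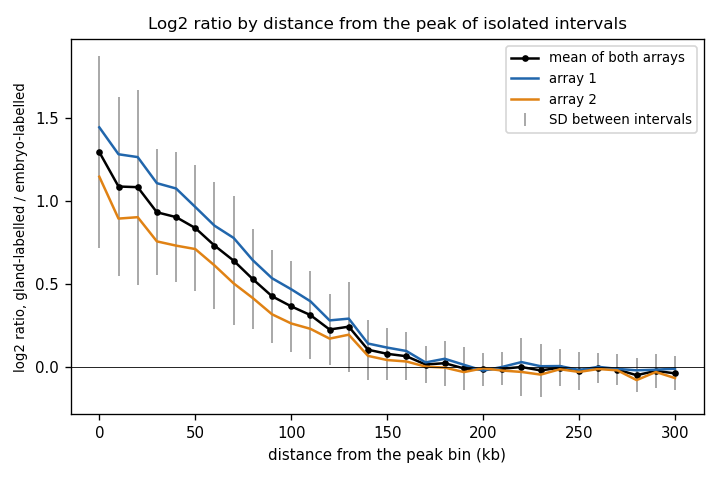
Mean log2 ratio (y axis) by distance from the peak bin (x axis, kb) over 22 isolated intervals, with a black line for the mean of both arrays, coloured lines for each array and bars for the SD between intervals. The mean falls from 1.30 at the peak to 0.37 at 100 kb and -0.01 at 200 kb.

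The probes in the intervals were slightly poorer in GC than those elsewhere. Their mean bin GC content was 40.8%, against 41.6% elsewhere (rotation of the intervals along the genome, two-sided, adjusted p = 4e-04 over 2 measures, 10000 rotations; 95% of rotations gave 41.2% to 41.8%). The intervals had 15.2 probes per bin against 15.6 elsewhere, within the range of 15.1 to 15.8 that held 95% of rotations, although the two-sided p around the genome mean was 0.03.

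The 7 called lower bins were single bins with small ratios: 3 on X, 3 on 3R and 1 on 3L. The lowest was X 1410001 to 1420000, with a mean log2 ratio of -0.62 ± 0.45 (limma adjusted p = 0.00852), and the one with the smallest adjusted p was 3L 21640001 to 21650000, at -0.59 ± 0.03 (limma adjusted p = 0.000577). Their number changed with the setting: bins of 20 kb gave 0, bins of 5 kb gave 88.5 in units of 10 kb, and loess within each array gave 4.

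The authors' deposited list holds 65 intervals called troughs, covering 12270 kb, and was used to ask whether the same positions stand out in both arrays. For 22 of them, 16 on 3R and 6 on 2L, both edges fell exactly on probe edges of the array files once 25 kb was taken off each side; only these were compared, because the list names its build (FlyBase r5.1) and the array files name none. All 22 had a mean log2 ratio above 0 on both arrays by the labels' dyes, and the median over the 22 was 0.41 on array 1 and 0.21 on array 2 (mean 0.29, SD of the arrays' medians 0.14). Rotated positions gave medians of -0.15 to -0.02 in 95% of 10000 rotations (permutation by rotation, two-sided p = 1e-04, the smallest they can give). The list was called by the authors on data of this series and is not independent evidence. In the authors' deposited table of normalized values, a score with a standard deviation of 1, the same 22 had negative means, from -1.29 to -0.28. That table covers 1 array and followed red over green of array 1 at r = 0.989 across probes, which are not independent replicates; by the labels, red was the embryo channel there.

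Of the 22 troughs compared, 12 held at least 1 called bin and 10 held none; the stronger the authors' score, the higher the mean log2 ratio (Spearman rho = 0.939 across the troughs, on a score made from the same data). In the other direction, all 12 intervals found on 3R and on 2L up to 12.96 Mb overlapped one of these troughs. Of the 22 compared, the strongest was 3R 12492821 to 12798118, with a mean of 0.78 ± 0.13 over its whole length. Next came 3R 6726481 to 6999470 with 0.75 ± 0.25 and 3R 23817571 to 24114968 with 0.65 ± 0.17. The highest score among the 22 was 516.78, against 3000 in the whole list, so the strongest troughs of the list were not compared. All trough means and coverages were taken over the deposited edges, including the 25 kb on each side that the edge match takes as flank. In the shortest of the 22, of 50.04 kb on 3R, nearly the whole span was flank, so low values do not show that the core was low. The 10 troughs without a called bin had means of 0.18 to 0.27, and the lowest mean among those with one was 0.26. The 3 with the highest scores among them were 2L 3902871 to 4023140 at 0.25 ± 0.14, 3R 16166031 to 16320107 at 0.23 ± 0.12 and 3R 13032041 to 13169310 at 0.25 ± 0.09. Requiring called bins over at least 50% of a trough left 5 of the 22.

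Toward the centromeres, the ratio was highest on 2L and 2R and near 0 on 3L and 3R. The outermost 1 Mb covered by probes had a median log2 ratio of 0.46 ± 0.04 (SD, n = 2) on 2L, 0.22 ± 0.01 on 2R, 0.09 ± 0.02 on X, 0.02 ± 0.01 on 3L and -0.002 ± 0.031 on 3R. These windows held 1517 probes on 3L and 1444 on 3R, against 1039 on X, 1031 on 2L and 965 on 2R. They were thus not alike in probe coverage, and whether this bears on the differences between arms was not tested. Of the 439 bins in these 5 windows, 65 were called higher: 32 on 2L, 22 on 2R, 8 on X, 3 on 3L and 0 on 3R. In the same windows 2 bins were called lower, both on 3R, at 1 to 10000 and 710001 to 720000. At the telomere-proximal ends (200 kb) the median was 0.30 ± 0.18 on 2R and at most 0.11 on the other arms. Averaged over the 5 arms, the proximal windows were at 0.16 ± 0.02 and the distal windows at 0.10 ± 0.05. These values and the arm medians were left untested: an exact permutation test of 2 arrays cannot go below a two-sided p of 0.5, and no model was fitted to them.

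Whole arms differed little. The median log2 ratio of X was below that of 2L, 2R, 3L and 3R pooled by 0.18 on array 1 and 0.05 on array 2, a mean difference of -0.11 ± 0.09 (SD, n = 2) that is of the size of the spread between arrays. Chromosome 4 lay above the same arms by 0.16 and 0.06 (mean 0.11 ± 0.07). The median of 2L was 0.06 ± 0.02, and those of 2R, 3L and 3R were between -0.002 and 0.013.

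The same intervals were high on both arrays, with smaller ratios on array 2. Across bins, which are not independent replicates, Pearson r was 0.841 over all bins, 0.922 over the called higher bins and 0.421 over the 9889 uncalled bins more than 100 kb from a call. The called bins span a wider range of ratios by the way they were chosen, which raises their r. Single probes correlated at r = 0.475. In the intervals array 2 reached 0.753 of the log2 ratio of array 1 (95% bootstrap interval over intervals 0.721 to 0.777). When array 2 was turned the opposite way, so that dye effects add and the difference between the DNAs cancels, limma called 0 bins and 3 had an unadjusted p below 0.05. That fit counts the difference shared by the arrays as spread, also away from the intervals, so it has little power and its lack of calls says little about dye effects. By size alone, 12 bins reached 0.5 in it, against 576 in the labelled orientation.

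**Figure D4:**
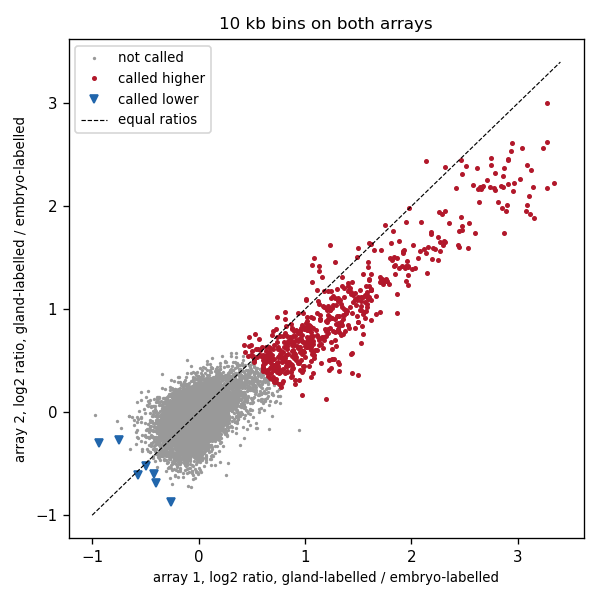
Log2 ratio of each 10 kb bin on array 1 (x axis) and array 2 (y axis), both as the channel labelled salivary gland over the channel labelled embryo, with the dashed line at equal ratios. The called higher bins run along a band below the dashed line (r = 0.922), with array 1 reaching 3.34 and array 2 reaching 3.00.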

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

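The settings with the direction turned on both arrays, and all counts of higher intervals and of bins at or above 1, were chosen after seeing the data. Turning the direction exchanges the counts by construction: 569 bins were then lower and 7 higher, 273 lay at or below -1 and 0 at or above 1, with 36 lower and 0 higher intervals, and the values became -0.295 for the troughs, 0.115 for X minus autosomes, -0.159 for the proximal ends and -0.104 for the telomere-proximal ends. Called higher bins numbered 551 to 586 under the alternatives that changed signals, filters, centring, GC content, bin size or variance prior, and loess shared 530 of its 554 with the 569. The number of higher intervals varied more, from 31 to 48 against 36. It was 31 with autosomal centring and with bins of 20 kb, and 48 with bins of 5 kb. The minimum of 3 called bins spans a different length at each bin size. With a minimum effect of 1 the called higher bins fell to 273 in 18 intervals and the lower bins to 0, since fewer bins can pass. The 7 lower bins became 88.5 (in units of 10 kb) with bins of 5 kb, 0 with bins of 20 kb and 4 with loess, and bins of 5 kb put 5.5 at or below -1; the cause was not tested, but smaller bins rest on fewer probes. The median of the proximal ends was 0.133 with loess and 0.14 with autosomal centring, against 0.159, and the cause was not tested beyond the small spread (SD 0.0167) of that value. The 11 troughs with the stronger scores had a median of 0.449, against 0.295, and 5 troughs in place of 12 counted as shared when at least 50% had to be covered, both by construction. The 12 named bins kept their direction and calls and the 3 named troughs their direction under each of the 5 alternatives that give them a value. The adjusted p of these bins moved far more than their ratios. For the highest peak, on 2R at 1.93 Mb, the limma adjusted p ran from 1.97e-08 to 3.63e-33 at mean log2 ratios of 3.12 to 3.27. The size of an adjusted p is thus no stable measure of strength here. With 1 array left there is no test, so calls and intervals have no value; without replicate 1 or replicate 2 the bins at or above 1 numbered 211 to 352, none lay at or below -1, and the values were 0.209 to 0.408 for the troughs, -0.18 to -0.0496 for X minus autosomes, 0.147 to 0.171 for the proximal and 0.0671 to 0.141 for the telomere-proximal ends. No paired analysis was possible because there is a single group. Not run were the authors' normalized values, whose scale is not log2, and the gene lists with their alternatives, for which no annotation was used here. Signal over background set no limit on the counts: requiring probes well above background and not saturated left 569 higher and 7 lower bins.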

Other observations

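Some called bins stood outside the intervals. Of the 25 such bins, 3 on X near its centromere-proximal end were among the highest: X 21600001 to 21610000 at a mean log2 ratio of 2.55 ± 0.76 (SD, n = 2), X 21540001 to 21550000 at 1.85 ± 0.38 and X 21630001 to 21640000 at 1.79 ± 0.04. On 2R, the bin 1800001 to 1810000 stood at 2.51 ± 0.79, near the interval with the highest peak. The first bin of X, 1 to 10000, stood at 1.43 ± 0.28, and X 11040001 to 11050000 at 1.17 ± 0.14 with no called neighbour. These bins were chosen after their values were seen.

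Far from any call, 800 of 154770 single probes were at or below -1 on both arrays and 152 at or above 1, while 12 and 3 were at such values in opposite directions. The log2 ratio outside the intervals also fell with signal on both arrays, from a median of 0.47 in the dimmest 10% of probes to -0.20 in the brightest on array 1, and from 0.31 to -0.64 on array 2.

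In the tests below, those of extra copies and exchanged dyes by slopes within intervals, of DNA not yet copied in embryo nuclei, of an additive background with the trend on signal removed, of a signal-dependent trend, of mixed DNA and of the sex ratio were chosen after the result was seen. The intervals were higher in the channel labelled salivary gland, the opposite of the underreplication known for this tissue, and the tables argue against dye bias (12 bins of at least 0.5 in size with array 2 turned the opposite way, against 576) and probe GC content (571 called bins after correction, against 569). They argue also against extra copies in the gland-labelled DNA as the main source: across the bins within each interval, with signals adjusted for probe GC content and set against the log2 ratio of the other array, that channel carried a share of the slope of the ratio of -0.0419 on array 1 and 0.0555 on array 2 (95% bootstrap interval over intervals -0.117 to 0.15), and the embryo-labelled channel, which by construction carries the rest, 1.04 and 0.945 (0.85 to 1.12), as dyes exchanged in the labels of both arrays would give. Mean signals in the intervals depend on which probes lie there, but the embryo-labelled channel lay 0.92 log2 units or more below the other probes on each array, with GC adjustment or without, against -0.32 at the lowest of 10000 rotated positions (GC-adjusted); the gland-labelled channel lay 0.18 and 0.07 above them with GC adjustment, 0.20 and 0.06 above their mean without it and 0.15 and 0.03 below their median, which on array 1 was each time higher than all rotated positions of that channel (at most 0.17, 0.18 and -0.16), so a small rise of that channel, a share of 0.139 of the GC-adjusted ratio on array 1 (0.0916 to 0.194), stays open. DNA not yet copied in cycling embryo nuclei lies at most 1 log2 unit below copied DNA. It is argued against for 5 intervals, 4 on 2L and 1 of 3 bins on 2R. Their median over all bins was above 1 on both arrays beyond its 95% bootstrap interval, which treats neighbouring bins as independent. By this measure uncopied DNA stays open for the other 31. Some of their peak bins also passed 1 on both arrays, such as 2L 14790001 to 14800000 (1.95 and 1.85) and 2R 440001 to 450000 (1.62 and 1.63). These bins were chosen for their height, so they do not decide the question for whole intervals. A candidate explanation is thus that the dyes were recorded the other way round on both arrays and that the intervals are underreplicated in the gland; a true loss from the embryo DNA would give the same signals and was not tested.

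The ratios in the intervals were smaller on array 2 than on array 1, at 0.753 of them. An additive background would compress dim probes most. With the trend on signal of the probes outside the intervals removed from each array, the dimmest of 3 equal parts of the probes, set on the gland-labelled signal, was the least compressed. The ratio of the arrays was 0.858 there, 0.717 in the middle and 0.734 in the brightest part, with no steady trend. Brightest minus dimmest was -0.124 (95% bootstrap interval -0.157 to -0.0871). A constant added to the signals of array 1 until its ratios shrank to 0.753 gave 0.274. That simulated array shared the probe noise of array 1, unlike the real array 2, and the parts were not set on the embryo-labelled signal. The parts thus do not settle whether an additive background played a role. A signal-dependent trend on array 2 left the ratio at 0.768 once removed by loess. Unaltered DNA mixed into the DNA with lost copies would lower the ratio in the highest bins. It was higher there by 0.11 (0.671 in called bins under 1 and 0.781 in the 65 of at least 2). The bootstrap interval of this rise, 0.0743 to 0.144, resampled single bins. Neighbouring bins of an interval are not independent, so it is too narrow and only the size of the rise is used. Mixtures of the reverse kind would give such a rise: unaltered DNA in DNA with extra copies is argued against by the share of 0.0555 above, but DNA with lost copies in the other sample of array 2 stays open, since the gland-labelled channel, which it would make fall within intervals, had a slope there of 0.04 (-0.0803 to 0.105) and the size of the fall to expect is not known. Normexp in place of the background correction of Feature Extraction brought the ratio to 0.853 (0.82 to 0.88), so that correction may account for part of the gap and cannot be told apart here from the different software and scan settings of the arrays, and a difference between the extractions stays open as an untested biological explanation.

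The X lay below the autosomal arms by a small amount. Probe GC content did not account for it, since the difference was -0.115 before and -0.115 after correction. A different sex ratio of the animals behind the DNA samples could give a difference of this size, but the labels give no sex and the array has 0 probes on the Y, so this cannot be told apart from an array effect, given that array 1 and array 2 differed from each other by about as much as the value itself.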
